A study of Solanum lycopersicum with 32 samples.

How the data were processed

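RNA-seq counts of tomato stems were analysed for 32 libraries, 2 for each of 16 groups. Per the labels' protocols, each sample held mid-segments of internodes from plants chosen for their uniformity, harvested in duplicate after dawn; RNA was extracted with a column kit and treated with DNase, libraries were made with the TruSeq RNA v2 kit, and single 50 bp reads were taken on a HiSeq instrument. The values are whole-number counts of reads per gene, deposited by the authors in one table for the overexpression, graft, FUL and Ginkgo experiments (34728 lines) and another for the heat-shock experiment (34825 lines, with 96 microRNA lines and 1 line for Arabidopsis FT). Per the submitters' processing notes, FastQC 0.11.5, Trim Galore, TopHat2 2.1.0, Bowtie2 2.2.6 and HTSeq 0.6.1 were used. Their roles, settings and order, the strand setting and the genome build are not given in the sources used here, so no coordinates are printed. The kit does not mark strand, so reads of overlapping or antisense genes cannot be told apart, and reads shared by near-identical genes, such as members of one gene family, may have been split or dropped at counting. Each column of both tables matched the labels of 1 sample, and 0 columns of per-sample values were left unused.

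Groups were taken from the titles and genotype labels. Where these disagree the choice was fixed before the data were examined: overexpression samples titled sft carry the genotype label SFT and were treated as the sft mutant; samples titled pTFT carry the genotype label pSFT-SFT, which was used; grafts titled recipient//donor were named donor//recipient as in their genotype labels; and the grafts titled with a wt partner but labelled sft//sft were used as sft//sft. Counts of both libraries of each group were compared by a chi-square test over genes with 100 or more reads in the pair. The statistic per degree of freedom lay between 7.25 and 47.6, so no pair looked like one library deposited in duplicate. The test does not tell separate plants from separate preparations of one pool. In the FUL, Ginkgo and heat-shock experiments, both libraries of a group carry the same label number, with a letter B for 1 of them. Overexpression and graft libraries each carry a number of their own. Whether a shared number marks separate preparations of one sample is not stated. Each library counted as 1 replicate because the labels list it as a sample of its own.

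All tests used the counts as deposited, in R 4.3.3. The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) with TMM normalization and filterByExpr by group (minimum count 10, minimum total 15), fitted to all groups of an experiment so that they share 1 estimate of the spread. For 35S:GinFT the fit held the FUL and Ginkgo groups together. Genes tested numbered 21141 in the overexpression, 21566 in the graft, 21312 in the FUL, 21458 in the FUL and Ginkgo, and 20546 in the heat-shock fits. P-values were adjusted by Benjamini and Hochberg within each of 18 comparisons, and genes with an adjusted p under 0.05 were called changed. Differences between responses (35S:SFT donor in sft against WT recipients, heat in pHS:FT against sft plants) were tested as contrasts of 4 groups. CPM are counts scaled to a common total after TMM normalization. Where every library of a group stood at 0 reads, the fold is a lower bound computed with 3 reads in each library of that group.

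The genes named in the text were chosen by a rule written before the data were examined: the largest rises and falls among called genes with a mean log2 CPM of 2 or more whose groups do not overlap, the genes of the transgenes and mutants in the comparisons that involve them, and all genes where fewer than 5 were called. Because the files do not pair identifiers with names, at most 2 rises and 2 falls are printed per comparison. The reference table of gene names matched 0 of the identifiers. For the 6 identifiers tied to names beforehand, the chromosome in the identifier is that of the symbol in the reference table in 6 of 6, which does not establish the pairing. Gene lists for secondary wall, xylan, lignin, laccase, fasciclin, cell death and cambium genes had been planned and were not run for the same reason.

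After seeing the data, sets were formed from the genes higher or lower in heated pHS:FT against heated sft plants and tested in the other experiments with camera of limma 3.58.1 (preset correlation 0.01, and with an estimated correlation) and with fry, adjusted over the sets tested in a comparison. Sets formed in the same way from the other experiments were tested alongside and are not reported one by one. Overlaps between lists were compared with the product of the list sizes over the genes tested in both, per direction. For comparisons against the same WT libraries, unchanged groups were simulated 20 times against those libraries and the correlation, covariance and overlap recorded.

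The main procedure was tested on simulated counts with the means, spread and library sizes of the real ones and 200 genes changed. These 200 were drawn from genes with a mean of 2 CPM or more over the libraries of the fit, so recovery below that level was not measured. It recovered 82% of genes changed 2-fold and 100% of those changed 4-fold for the libraries labelled pSFT-SFT against WT (11.7% of calls were false), 52% and 93% for grafts with an sft recipient (7.1%), 56% and 94% for 35S:SFT against WT (10.2%), 62% and 94% for 35S:GinFT against WT (4.3%), 65% and 95% for heated pHS:FT against heated sft (8.6%), and 24% and 84% for the difference in heat response (12.2%).

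The alternatives tried were DESeq2 1.42.0, DESeq2-style size factors in edgeR, no filter on low counts, a filter of 1 CPM in 2 libraries, the replicate number or the run of library numbers as a block, only the groups compared in the fit, and leaving out each library in turn. Their effect is given in the closing section. Total counts of 16583755 to 45790153 put the limit of a count of 0, taken as 3 reads, at 0.0655 to 0.181 CPM.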

Results

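RNA was sequenced from tomato stems in 32 libraries, which fell into 16 groups of 2 libraries over 5 experiments. The series title and labels place the experiments around florigen, the mobile flowering signal that tomato makes from the gene SINGLE FLOWER TRUSS (SFT), a relative of Arabidopsis FT. The overexpression experiment held wild-type (WT) stems, stems of the sft mutant and libraries labelled pSFT-SFT. The graft experiment held 5 donor//recipient combinations, written donor first as in the genotype labels. The FUL experiment held WT, 35S:SFT and 35S:TFUL2 stems, in which the strong 35S promoter drives SFT or the MADS-box gene FUL2. The Ginkgo experiment held only 35S:GinFT stems, and the heat-shock experiment held sft plants with and without a heat-inducible Arabidopsis FT transgene (pHS:FT), each with and without heat. Total counts per library lay between 16583755 and 45790153, and the 10 most abundant genes took 3.2% to 5% of them. A gene with 0 reads could therefore have stood at up to 0.0655 to 0.181 CPM (counts scaled to a common library total), taking 3 reads as the limit that a count of 0 allows. These limits cover counting error only.

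The files identify genes by Solyc identifiers and do not pair these with names. Before the data were examined, 6 identifiers were tied to names from published knowledge of the genes: SFT (Solyc03g063100), its antagonist SELF PRUNING or SP (Solyc06g074350), and the FRUITFULL-clade MADS-box genes FUL1 (Solyc06g069430), FUL2 (Solyc03g114830), MBP10 (Solyc02g065730) and MBP20 (Solyc02g089210). The transgenic libraries themselves bore on 2 of these names, SFT and FUL2, and the other names rest on that published knowledge alone. Fold changes below are log2 values with their standard errors (SE) from edgeR's quasi-likelihood test, levels are mean CPM ± SD with n = 2 libraries, and adjusted p-values are Benjamini-Hochberg values over all genes tested. "Changed" means an adjusted p under 0.05. The labels' protocols speak of independent stem samples taken in duplicate, without saying whether the 2 libraries of a group came from different plants, so the p-values measure only the spread between these libraries, part of which may be technical.

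The transgenes were read first, as a check on the labels. SFT stood at 61.9 ± 3 CPM in 35S:SFT stems and at 0 reads in both WT libraries of that experiment, at least 524-fold higher (adjusted p = 0.00075). FUL2 stood at 1310 ± 229 CPM in 35S:TFUL2 stems against 3.45 ± 1.55 CPM in WT, 373-fold higher (log2 8.54, SE 0.35, adjusted p = 0.0011). The Arabidopsis FT row held 57 and 70 reads in heated pHS:FT libraries, 1 and 1 in unheated ones, 0 and 0 in heated sft libraries, and 12 and 0 in unheated sft libraries, which should lack the transgene. Florigen is mobile and only stems were read, so low SFT transcript does not show a label to be wrong. SFT transcript did not bear out the label of the libraries labelled pSFT-SFT. SFT was lower there than in WT, at 1.14 ± 0.141 against 2.51 ± 0.417 CPM (log2 -1.14, SE 0.24, adjusted p = 0.023), although edgeR no longer called that difference when any of the 4 libraries was left out (adjusted p 0.054 to 0.11). Every direction given below for this group is therefore that of the libraries labelled pSFT-SFT, not of plants shown to carry more SFT transcript. SFT transcript itself did not differ between sft and WT stems beyond the replicate spread (log2 -0.05, SE 0.22, adjusted p = 1), so it does not check the sft label. Mean SP was 0.6 ± 0.146 CPM or less in every group and was too low to test in the overexpression, graft and heat-shock experiments.

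**Figure D1:**
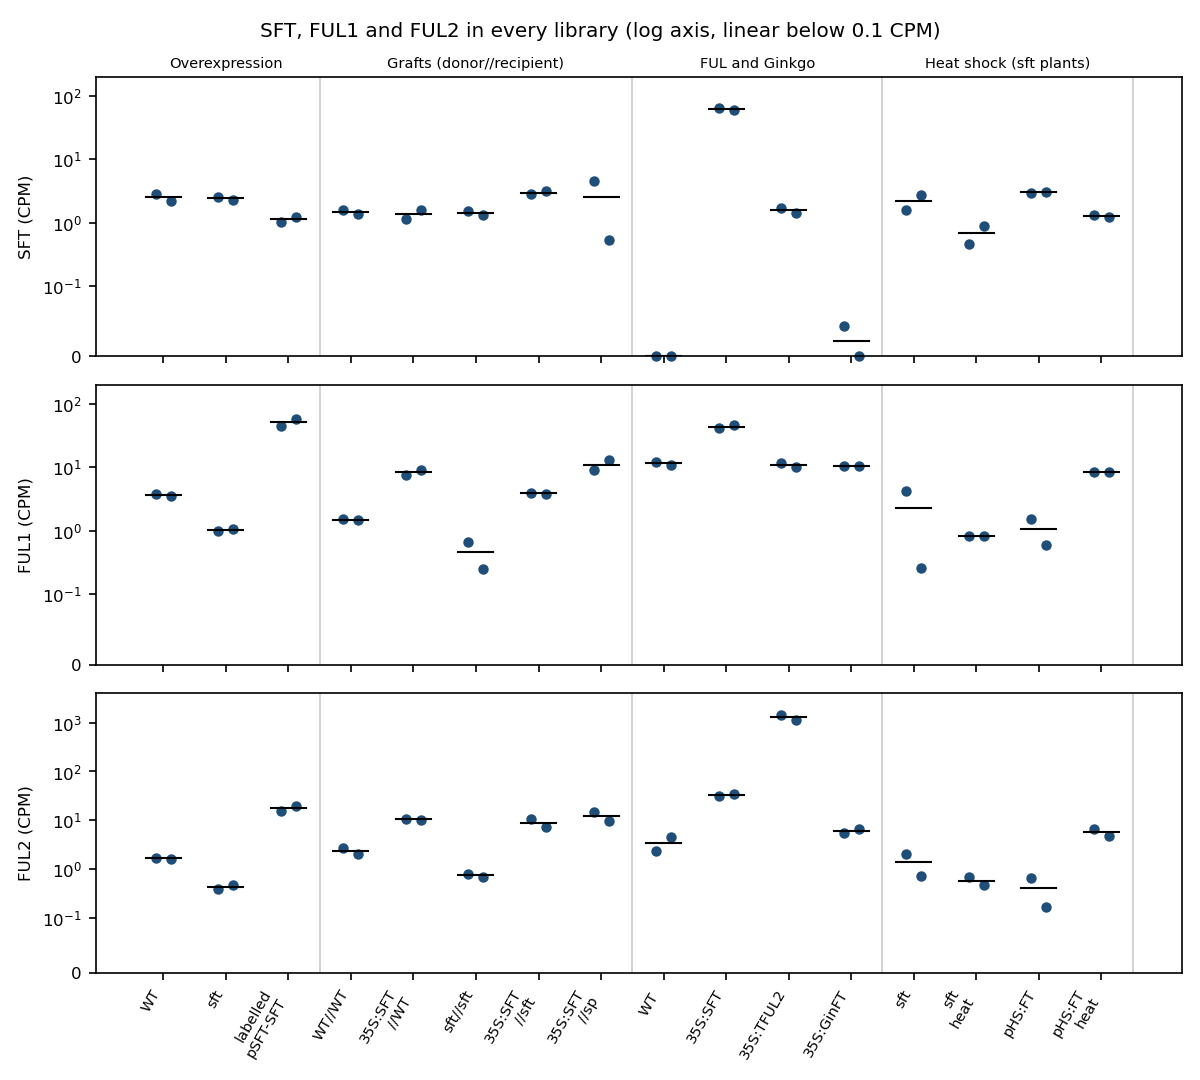
Level of SFT, FUL1 and FUL2 (CPM, log axis that is linear below 0.1) in each of the 32 libraries (points), with the group mean (line). SFT is highest in 35S:SFT stems (mean 61.9 CPM) and at 0 in WT of the FUL experiment, and FUL2 is highest in 35S:TFUL2 stems (mean 1310 CPM).

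The overexpression experiment addressed what more florigen, or its loss, does to the stem transcriptome. In the libraries labelled pSFT-SFT, each of the 4 FRUITFULL-clade genes was higher than in WT. FUL1 rose from 3.66 ± 0.143 to 51.4 ± 9.37 CPM (log2 3.81, SE 0.16, adjusted p = 0.00019) and FUL2 from 1.68 ± 0.0923 to 17.5 ± 3.02 CPM (log2 3.38, SE 0.18, adjusted p = 0.00033). MBP10 rose by log2 2.79 (SE 0.23, adjusted p = 0.0014), and MBP20 went from 1 and 2 reads to 34 and 37 (adjusted p = 0.0026). Across the transcriptome, 3760 of 21141 genes changed, 1911 higher and 1849 lower, and 1635 of them changed by 2-fold or more. Among 28 genes read or not read in whole groups, described below, these libraries differed from their WT at 25. The changes may thus hold differences between these plants other than florigen, which cannot be told apart from its effect here. The largest changes were of genes read in one group only. Solyc09g075690 stood at 20.4 ± 3.32 CPM against 0 reads in WT, at least 250-fold higher, and Solyc12g042240 was at least 202-fold higher. Solyc01g056370 was at 0 reads against 8.64 ± 0.964 CPM, at least 86-fold lower, and Solyc05g021180 was at least 75.7-fold lower. Against sft stems the same libraries differed at 4092 genes, 2173 higher and 1919 lower, with FUL1 higher by log2 5.64 (SE 0.18, adjusted p = 9.1e-05) and FUL2 by log2 5.3 (SE 0.22, adjusted p = 0.00018). The count against WT fell to 1742 or 2057 without replicate 1 or 2 of the libraries labelled pSFT-SFT and to 2184 or 1270 without replicate 1 or 2 of WT. The count against sft fell to 2200 or 2501 without replicate 1 or 2 of the libraries labelled pSFT-SFT and to 1895 or 2027 without replicate 1 or 2 of sft.

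Between sft and WT stems few genes were called. FUL1 stood at 1.03 ± 0.0716 CPM in sft against 3.66 ± 0.143 CPM in WT (log2 -1.83, SE 0.19, adjusted p = 0.077) and FUL2 at 0.443 ± 0.0665 against 1.68 ± 0.0923 CPM (log2 -1.93, SE 0.24, adjusted p = 0.13), so neither passed the test over all genes. The edgeR test called 12 genes, 3 higher and 9 lower, against 1056 genes with an unadjusted p under 0.05. Among the rises were Solyc06g005820 (log2 1.69, SE 0.14, adjusted p = 0.032) and Solyc06g074620 (log2 1.39, SE 0.08, adjusted p = 0.013), and among the falls Solyc06g083500 (log2 -3.3, SE 0.19, adjusted p = 0.013) and Solyc11g066090 (log2 -2.01, SE 0.12, adjusted p = 0.013). DESeq2 called 82 genes, and edgeR called 42 or 1 without WT replicate 1 or 2, and 0 without either sft replicate. One label field names this group sft and another SFT, and the groups were taken from the titles.

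The grafts asked whether florigen supplied by a 35S:SFT donor changes the stem of an sft, WT or sp recipient. With an sft recipient, FUL2 stood at 9 ± 2.4 CPM in 35S:SFT//sft against 0.757 ± 0.0594 CPM in sft//sft (log2 3.56, SE 0.31, adjusted p = 0.067), and FUL1 at 3.89 ± 0.082 against 0.456 ± 0.291 CPM (log2 3.04, SE 0.36, adjusted p = 0.18). With a WT recipient, FUL2 stood at 10.4 ± 0.375 CPM in 35S:SFT//WT against 2.43 ± 0.479 CPM in WT//WT (log2 2.1, SE 0.27, adjusted p = 0.15), and FUL1 at 8.43 ± 1.04 against 1.5 ± 0.00711 CPM (log2 2.49, SE 0.32, adjusted p = 0.15). Each library with the 35S:SFT donor was above each one without it for both genes, yet none of these differences passed the test over all genes in the fit without a block. SFT itself stood at 2.98 ± 0.273 CPM in 35S:SFT//sft against 1.43 ± 0.156 CPM in sft//sft (log2 1.05, SE 0.76, adjusted p = 0.96) and at 1.36 ± 0.316 CPM in 35S:SFT//WT against 1.47 ± 0.165 CPM in WT//WT (log2 -0.12, SE 0.78, adjusted p = 1). No graft library held SFT above 4.51 CPM, where 35S:SFT stems of the FUL experiment stood at 61.9 ± 3 CPM. The labels do not say which partner's stem was sampled, though these SFT levels argue against stems of the 35S:SFT donor. For sft recipients edgeR called 0 of 21566 genes (1066 at an unadjusted p under 0.05; DESeq2 called 42, 22 higher and 20 lower), and 2 without sft//sft replicate 2. For WT recipients it called 3 genes, all lower and each with an adjusted p of 0.045: Solyc12g098760 (log2 -1.33, SE 0.13), Solyc09g098510 (log2 -1.33, SE 0.12) and Solyc03g020030 (log2 -3.03, SE 0.28). DESeq2 called 90 genes there, and edgeR 0 when any of the 4 libraries was left out. The graft libraries carry label numbers in an early and a late run, and with that run as a block edgeR called 5 genes for sft recipients, FUL2 among them (log2 3.56, adjusted p = 0.035; FUL1 adjusted p = 0.079), and 12 for WT recipients (FUL1 adjusted p = 0.056, FUL2 adjusted p = 0.081). The sft//sft group carries another donor in its titles than in its genotype label, so its donor is not settled.

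The response to the 35S:SFT donor was not shown to differ between sft and WT recipients. A test of the difference called 0 genes in edgeR (826 at an unadjusted p under 0.05; DESeq2 called 19) and 1 without sft//sft replicate 2, and FUL2 differed by log2 1.46 (SE 0.41, adjusted p = 1). Between the control grafts, sft//sft and WT//WT, edgeR called 2 genes, Solyc06g017860 higher (log2 5.67, SE 0.47) and Solyc11g066090 lower (log2 -2.04, SE 0.16), both with an adjusted p of 0.023. The latter was also lower in ungrafted sft stems. FUL1 (log2 -1.66, SE 0.38, adjusted p = 0.45) and FUL2 (log2 -1.67, SE 0.31, adjusted p = 0.32) were not called. Recipients carrying sp, the mutation of SP, differed from WT recipients under the same donor at 1 gene, Solyc12g087830 (log2 -1.73, SE 0.12, adjusted p = 0.012), with FUL1 and FUL2 at log2 0.39 (SE 0.29) and 0.23 (SE 0.25). DESeq2 called 117 genes between the control grafts and 15 between sp and WT recipients, and edgeR called 0 between the control grafts when any of the 4 libraries was left out. For sp against WT recipients it called 0 without either 35S:SFT//WT replicate or without 35S:SFT//sp replicate 1. With the run of label numbers as a block, edgeR called 7 genes between the control grafts and 2 between sp and WT recipients, and still 0 for the difference between sft and WT recipients.

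In the FUL experiment, 35S:SFT stems had 3.8 times the FUL1 and 9.52 times the FUL2 of WT stems. FUL1 rose from 11.6 ± 0.891 to 44 ± 3.19 CPM (log2 1.93, SE 0.12, adjusted p = 0.008) and FUL2 from 3.45 ± 1.55 to 33.5 ± 1.67 CPM (log2 3.25, SE 0.29, adjusted p = 0.014). MBP10 stood at 1.26 ± 0.525 against 0.118 ± 0.167 CPM and was not called (adjusted p = 0.12). In all, 370 of 21312 genes changed, 169 higher and 201 lower. Among the rises were Solyc09g007940 (log2 6.49, SE 0.5, adjusted p = 0.012) and Solyc06g084820 (log2 6.02, SE 0.23, adjusted p = 0.0011), and Solyc11g028080 and Solyc08g065460, at 0 reads in 35S:SFT, were at least 126-fold and 51.6-fold lower. The count rested on single libraries. It was 18 or 10 without 35S:SFT replicate 1 or 2, 1339 without WT replicate 1 and 281 without WT replicate 2, and without either 35S:SFT replicate FUL1 (adjusted p = 0.054 and 0.064) and FUL2 (adjusted p = 0.085 and 0.097) were no longer called. With only the groups compared in the fit it was 18, and DESeq2 called 1487.

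Stems carrying 35S:TFUL2 were set against the WT of the FUL experiment to ask what raised FUL2 does. FUL1 did not differ from WT beyond the replicate spread, at 11.2 ± 1.23 against 11.6 ± 0.891 CPM (log2 -0.04, SE 0.12, adjusted p = 0.86). SFT, at 0 reads in WT, stood at 1.59 ± 0.237 CPM, at least 13.4-fold higher (adjusted p = 0.0033). SFT was read in WT of the overexpression experiment (2.51 ± 0.417 CPM) and in WT//WT grafts (1.47 ± 0.165 CPM), and was at 1 and 0 reads in 35S:GinFT, so the 0 reads in this WT set it apart from the other WT groups. Changes were found at 2716 of 21312 genes, 1590 higher and 1126 lower. Among genes read or not read in whole groups, described below, 35S:TFUL2 differed from this WT at 11. It differed from WT of the overexpression experiment at 1. The changes may thus hold differences between these plants other than FUL2, which cannot be told apart from its effect here. Solyc05g016250 (at least 121-fold) and Solyc05g014190 (log2 7.12, SE 0.36, adjusted p = 0.0014) were among the rises, and Solyc06g008760 and Solyc04g016550 were at least 169-fold and 87.7-fold lower. Solyc05g016250 was at 2 CPM or more in every group except WT and 35S:SFT of this experiment, 35S:GinFT and the libraries labelled pSFT-SFT, where it was at 0 to 3 reads. In the libraries labelled pSFT-SFT against their WT, each of these 4 genes changed the opposite way (adjusted p 0.00019 for Solyc05g016250, 0.00031 for Solyc05g014190, 0.0008 for Solyc06g008760 and 0.0013 for Solyc04g016550). Between 35S:SFT and 35S:TFUL2 stems 1818 genes differed, 708 higher and 1110 lower in 35S:SFT, with FUL1 3.91-fold higher there (log2 1.97, SE 0.12, adjusted p = 0.002). The count for 35S:TFUL2 against WT was 461 or 280 without 35S:TFUL2 replicate 1 or 2, and 1332 with only the groups compared in the fit. That between both transgenic groups was 155 without 35S:SFT replicate 1, lower still without replicate 2, 529 or 100 without 35S:TFUL2 replicate 1 or 2, 3466 with only the groups compared, and 3064 in DESeq2.

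The lists of 35S:SFT and 35S:TFUL2 overlapped, with WT libraries common to both. Of 237 genes called in both, 109 were higher in both (12.6 for independent lists of these sizes) and 117 lower in both (10.6), while 11 went opposite ways. Their fold changes correlated across genes with r = 0.37. Over 20 simulations of unchanged groups, shared WT libraries alone gave r = 0.5 and 0 shared calls. The simulated covariance was 0.0552 against the observed 0.239, a difference of 0.183. Because no simulated gene was changed, 0 shared calls was built in and is no measure for the observed overlap. All simulated groups were drawn from the WT level, so a WT unlike the transgenic plants was not simulated. Part of the excess over independent lists may come from the shared controls, which were not split, since each part would hold 1 library, and genes are not independent replicates.

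The 35S:GinFT plants, labelled with a construct that is by its name an FT gene of Ginkgo, tested another FT gene in the same tissue. No row counted that gene, so its expression was not checked. These plants came from an experiment with no WT of its own and were set against the WT of the FUL experiment. The construct and the experiment therefore cannot be told apart. FUL1 stood at 10.5 ± 0.127 CPM against 11.6 ± 0.927 in WT (log2 -0.13, SE 0.12, adjusted p = 0.53) and FUL2 at 6.05 ± 0.735 against 3.44 ± 1.54 CPM (log2 0.79, SE 0.29, adjusted p = 0.15). Against 35S:SFT stems, both were lower, FUL1 by log2 -2.05 (SE 0.12, adjusted p = 0.00039) and FUL2 by log2 -2.46 (SE 0.27, adjusted p = 0.0017). SP was lower than in WT (log2 -2.73, SE 0.56, adjusted p = 0.038) and than in 35S:SFT (log2 -2.08, SE 0.59, adjusted p = 0.035), on 1 and 3 reads against 11 and 21 in WT and 11 and 10 in 35S:SFT. The difference from WT was not called when any of the 4 libraries was left out (adjusted p 0.071 to 0.2). Against WT, 1338 of 21458 genes changed, 547 higher and 791 lower, among them Solyc06g071650 (log2 7.37, SE 0.41, adjusted p = 0.0019) and Solyc01g109140 (log2 4.56, SE 0.87, adjusted p = 0.031) upward and Solyc09g089610 (log2 -3.89, SE 0.49, adjusted p = 0.0099) and Solyc11g022590 (log2 -3.69, SE 0.73, adjusted p = 0.034) downward. Against 35S:SFT, 6875 genes differed, 3583 higher and 3292 lower in 35S:GinFT. Of 80 genes called against WT in both 35S:SFT and 35S:GinFT, 57 moved opposite ways, with r = -0.03 across genes where shared WT libraries alone gave 0.5, and a covariance of -0.0127 against a simulated 0.0551. The count against WT was 194 or 496 without 35S:GinFT replicate 1 or 2, and 172 with only the groups compared. That against 35S:SFT was 2619 without 35S:GinFT replicate 1 and 2901 or 2155 without 35S:SFT replicate 1 or 2.

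**Figure D2:**
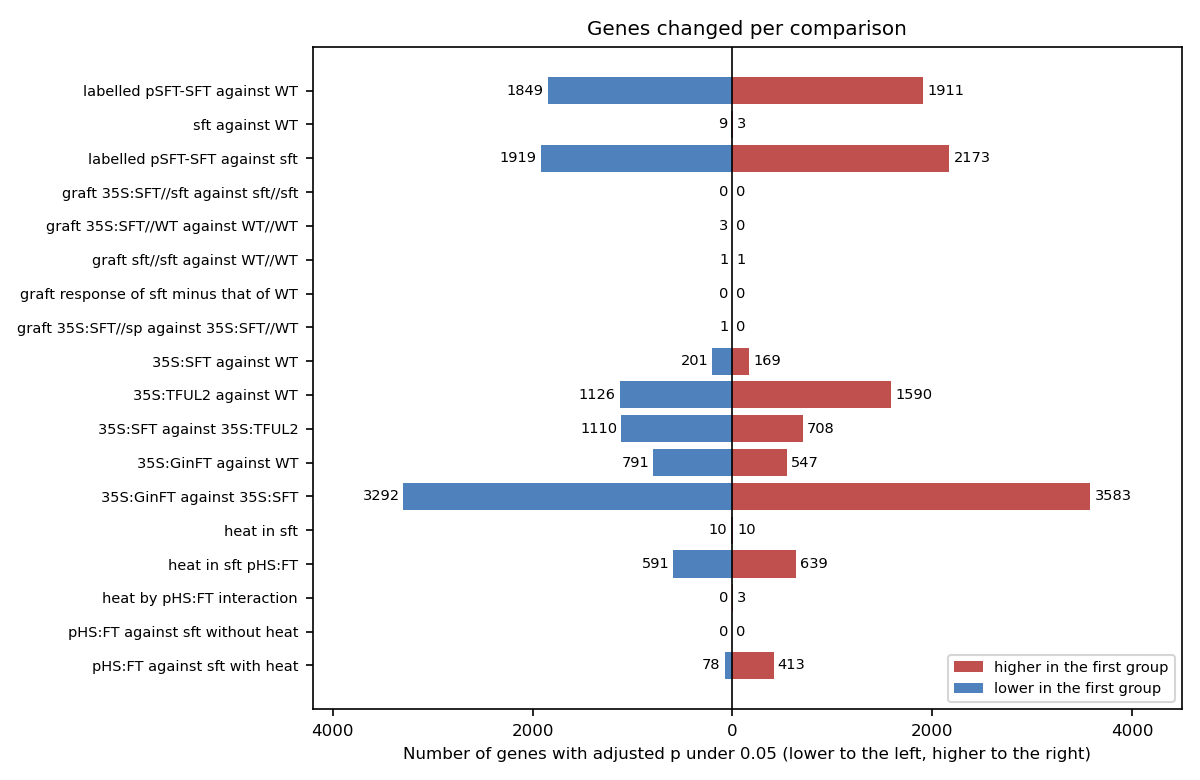
Number of genes with an adjusted p under 0.05 in edgeR for each comparison, lower in the first group to the left and higher to the right. Counts run from 0 in grafts with an sft recipient to 6875 for 35S:GinFT against 35S:SFT.

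The heat-shock experiment asked what a pulse of FT does in plants that lack their own florigen. Heat raised FUL2 in pHS:FT plants from 0.416 ± 0.349 to 5.73 ± 1.35 CPM (log2 3.78, SE 0.63, adjusted p = 0.021), and FUL1 went from 1.07 ± 0.674 to 8.44 ± 0.157 CPM without passing the test (log2 2.98, SE 0.92, adjusted p = 0.099). In sft plants without the transgene, heat left FUL2 at 0.583 ± 0.155 against 1.4 ± 0.931 CPM (log2 -1.29, SE 0.63, adjusted p = 0.59) and FUL1 at 0.824 ± 0.0103 against 2.26 ± 2.82 CPM (log2 -1.49, SE 0.97, adjusted p = 0.7). Unheated sft replicate 1, the library with 12 Arabidopsis FT reads, held 124 FUL1 reads against 6 in replicate 2, and without it FUL1 had a log2 change of 1.63 with heat in sft. Heat changed 1230 of 20546 genes in pHS:FT plants, 639 higher and 591 lower, and 20 genes in sft plants, 10 higher and 10 lower. In sft plants Solyc06g076560 rose from 12.1 ± 4.94 to 155 ± 8.54 CPM (log2 3.67, SE 0.44, adjusted p = 0.045) and Solyc01g105770 rose by log2 3.4 (SE 0.32, adjusted p = 0.017), while Solyc09g065660 (log2 -4.39, SE 0.34) and Solyc02g084790 (log2 -4.24, SE 0.29) fell, both with an adjusted p of 0.013. The count in pHS:FT plants was 90 or 31 without unheated pHS:FT replicate 1 or 2, 408 or 2088 without heated replicate 2 or 1, and 1441 without unheated sft replicate 1, a run chosen after seeing the data. That in sft plants was 1 or 0 without heated sft replicate 1 or 2, 41 or 146 without unheated sft replicate 1 or 2, and 253 in DESeq2.

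Tested directly, the response to heat differed between pHS:FT and sft plants at 3 genes, each with a more positive response in pHS:FT plants. These were Solyc02g084790 (log2 4.49, SE 0.35, adjusted p = 0.021), Solyc05g052400 (log2 3.14, SE 0.28, adjusted p = 0.037) and Solyc06g007240 (log2 1.7, SE 0.13, adjusted p = 0.021). The difference for FUL2 was log2 5.07 (SE 0.89, adjusted p = 0.2) and that for FUL1 4.47 (SE 1.33, adjusted p = 0.38). DESeq2 called 228 genes. In edgeR the count was 0 without any 1 of the unheated pHS:FT or heated sft libraries, 39 or 89 without unheated sft replicate 1 or 2, and 7 without heated pHS:FT replicate 1.

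With both kinds of plants heated, pHS:FT differed from sft at 491 genes, 413 higher and 78 lower. FUL2 was among the higher ones, at 5.73 ± 1.35 against 0.583 ± 0.155 CPM (log2 3.3, SE 0.61, adjusted p = 0.038). FUL1 stood at 8.44 ± 0.157 against 0.824 ± 0.0103 CPM and was not called (log2 3.35, SE 0.95, adjusted p = 0.13). The Arabidopsis FT row, at 3.36 ± 1.01 CPM against 0 reads, was at least 25.1-fold higher (adjusted p = 0.032). Without heat, edgeR called 0 genes between the same genotypes (1445 at an unadjusted p under 0.05; DESeq2 called 97), and 207 without unheated sft replicate 2. The count with heat was 17 or 28 without heated sft replicate 1 or 2, 897 without heated pHS:FT replicate 1, and 1007 in DESeq2.

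Heated pHS:FT plants differ from heated sft plants by the pulse of FT and by any other difference between the lines. The genes changed between them were followed into the other experiments, which share no libraries with them. These sets were formed after seeing the data, from a comparison that called 17 or 28 genes without heated sft replicate 1 or 2. Of the 413 higher genes, 249 of 406 measured were also higher in the libraries labelled pSFT-SFT against WT and 17 were lower, with a median log2 change of 0.88. With a 35S:SFT donor 82.7% of the set had a positive fold change in sft recipients (median 0.39) and 85.1% in WT recipients (median 0.45). In sft against WT only 14.8% were positive (median -0.21), as were 9.8% in sft//sft against WT//WT grafts (median -0.4). In 35S:SFT against WT the shift was small, with 61.6% positive, 11 of 404 genes called higher, 7 lower and a median of 0.08. In 35S:TFUL2 136 of 404 were higher and 23 lower (median 0.41), and in 35S:GinFT 5 of 405 were higher and 138 lower (median -0.51). The 78 lower genes had medians of the opposite sign to the higher ones in each of these comparisons, for example -0.45 in the libraries labelled pSFT-SFT and 0.52 in 35S:GinFT. Camera with its preset correlation of 0.01 called the higher set in each of these 8 comparisons, with adjusted p from 6.2e-38 (35S:GinFT) to 0.0043 (35S:SFT). With an estimated correlation it was called in 35S:TFUL2 (adjusted p = 0.031) and 35S:GinFT (adjusted p = 0.00054) and not in the libraries labelled pSFT-SFT (adjusted p = 0.14), in sft (adjusted p = 0.18), in grafts with sft and WT recipients (adjusted p = 0.23 and 0.18), in the control grafts (adjusted p = 0.34) or in 35S:SFT (adjusted p = 0.065). Fry, which tests whether the set moves one way on balance and does not compare it with other genes, called it in the libraries labelled pSFT-SFT (adjusted p = 0.014), 35S:SFT (adjusted p = 0.0063), 35S:TFUL2 (adjusted p = 0.00078) and 35S:GinFT (adjusted p = 4.1e-05), and not in sft (adjusted p = 0.23), grafts with sft and WT recipients (adjusted p = 0.3 and 0.23) or the control grafts (adjusted p = 0.39).

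**Figure D3:**
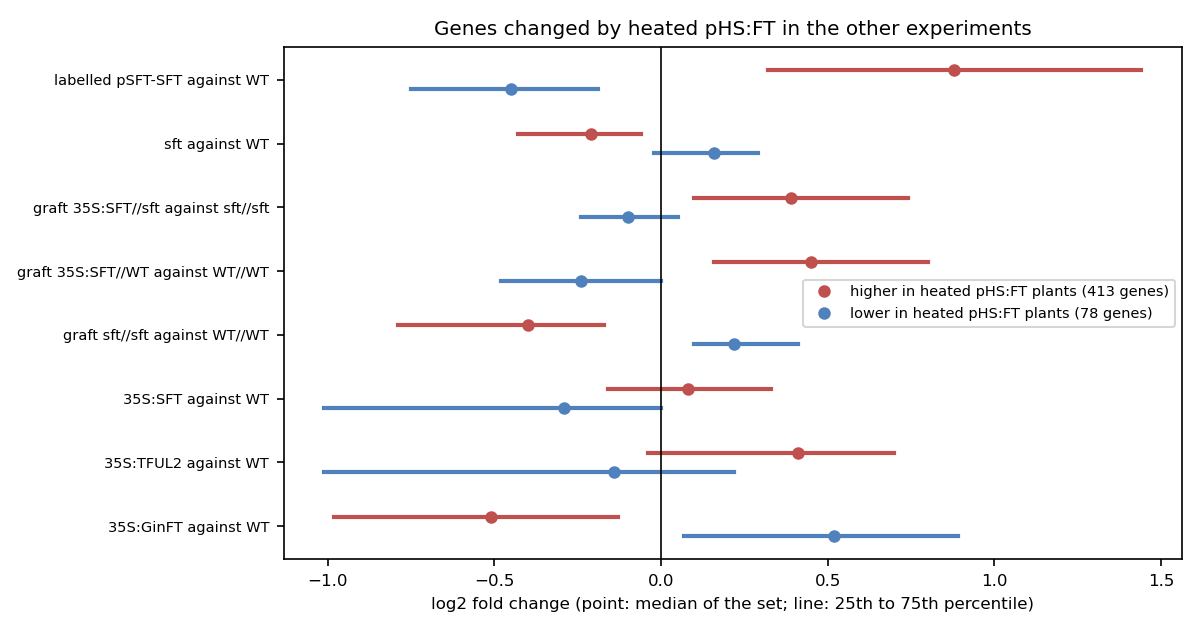
Log2 fold change, in the comparisons of the other experiments, of the 413 genes higher and 78 genes lower in heated pHS:FT against heated sft plants (points: median of the set, lines: 25th to 75th percentile over its genes). The higher set has a median of 0.88 in the libraries labelled pSFT-SFT and -0.51 in 35S:GinFT stems.

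The correlation of fold changes between the florigen comparisons was fixed as a measure of shared response before the data were examined. Across genes, r was 0.244 between the libraries labelled pSFT-SFT and 35S:SFT, 0.192 between the former and grafts with an sft recipient, and 0.105 between the former and the difference in heat response. It was 0.123 between those grafts and 35S:SFT, 0.053 between the grafts and the heat difference, and 0.068 between 35S:SFT and the heat difference. Leaving out 1 library turned the sign of the last 3: r was -0.036 for grafts with 35S:SFT without WT replicate 2 of the FUL experiment, -0.205 for grafts with the heat difference without 35S:SFT//sft replicate 1 (8 other libraries also turned it), and -0.001 for 35S:SFT with the heat difference without unheated pHS:FT replicate 2. The r of 0.192 fell to 0.041 without 35S:SFT//sft replicate 1. The libraries labelled pSFT-SFT and 35S:SFT stems shared 56 higher genes (13.9 for independent lists; Fisher's exact p = 1.1e-20) and 68 lower genes (17.1; Fisher's exact p = 2.1e-24), and 75.6% of the 164 genes called in both went the same way. With the difference in heat response, the planned partner, the libraries labelled pSFT-SFT shared 1 higher gene (0.255; Fisher's exact p = 0.23), where that difference had 3 called genes. A comparison with heated pHS:FT against heated sft plants was not planned. There the libraries labelled pSFT-SFT shared 249 higher (34.5) and 33 lower genes (6.8), and 94.3% of 299 went the same way. Genes are not independent replicates, so these tests describe the lists. The overlap with 35S:SFT also holds 33 genes changed 16-fold or more in the libraries labelled pSFT-SFT, 29 the same way and 4 opposite. For those genes the closing section weighs a difference in genetic background, and its part in the overlap was not tested.

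Genes that moved one way in each florigen experiment were few. In 4 comparisons with separate libraries (35S:SFT donors on sft and on WT, 35S:SFT stems, and heated pHS:FT plants), 15 of 19977 genes had a positive fold change and an unadjusted p under 0.05 in all 4, against 0.15 expected from independent lists, and 8 had a negative one, against 0.13. FUL1 and FUL2 were among the 15. Solyc03g019710 had log2 changes of 4.04, 3.67, 5.62 and 9.86 in that order, and Solyc09g009160 had 1.44, 2.55, 5.25 and 5.36. Solyc08g008360 (log2 -2.04, -1.68, -1.77 and -1.7) and Solyc08g074680 (log2 -0.98, -1.25, -2.69 and -1.59) were lower in each. These genes were picked after their values were seen, and 9 genes passed the same p in all 4 with mixed directions. In the libraries labelled pSFT-SFT, the 15 higher genes were also higher and 5 of the 8 lower genes lower, at the same p.

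Beside these changes stood genes that were either read or not read in whole groups. Over the 16 groups, 28 genes were at 2 CPM or more in both libraries of some groups and at 0 to 3 reads in both libraries of all the others. The libraries labelled pSFT-SFT differed from their WT at 25 of them, 35S:TFUL2 from its WT at 11, 35S:SFT from WT at 6, 35S:GinFT from WT at 1, and sft from WT, heated pHS:FT from heated sft and 35S:SFT//sft from sft//sft at 0. WT stems of the overexpression and FUL experiments, 2 groups with the same label, differed from each other at 10. WT of the overexpression experiment differed from WT//WT grafts at 0 and from 35S:TFUL2 at 1. Of the 28, 8 were at 0 to 3 reads in the libraries labelled pSFT-SFT and in WT, 35S:SFT and 35S:GinFT of the FUL and Ginkgo experiments but not elsewhere, and 4 stood at 2 CPM or more only in the libraries labelled pSFT-SFT. Solyc05g016250, named above for 35S:TFUL2, was among those 8. Solyc01g056370, Solyc08g065460 and Solyc11g028080, named above as lower in the libraries labelled pSFT-SFT or in 35S:SFT, were at 0 to 3 reads in both of these groups and at 2 CPM or more in all the others.

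**Figure D4:**
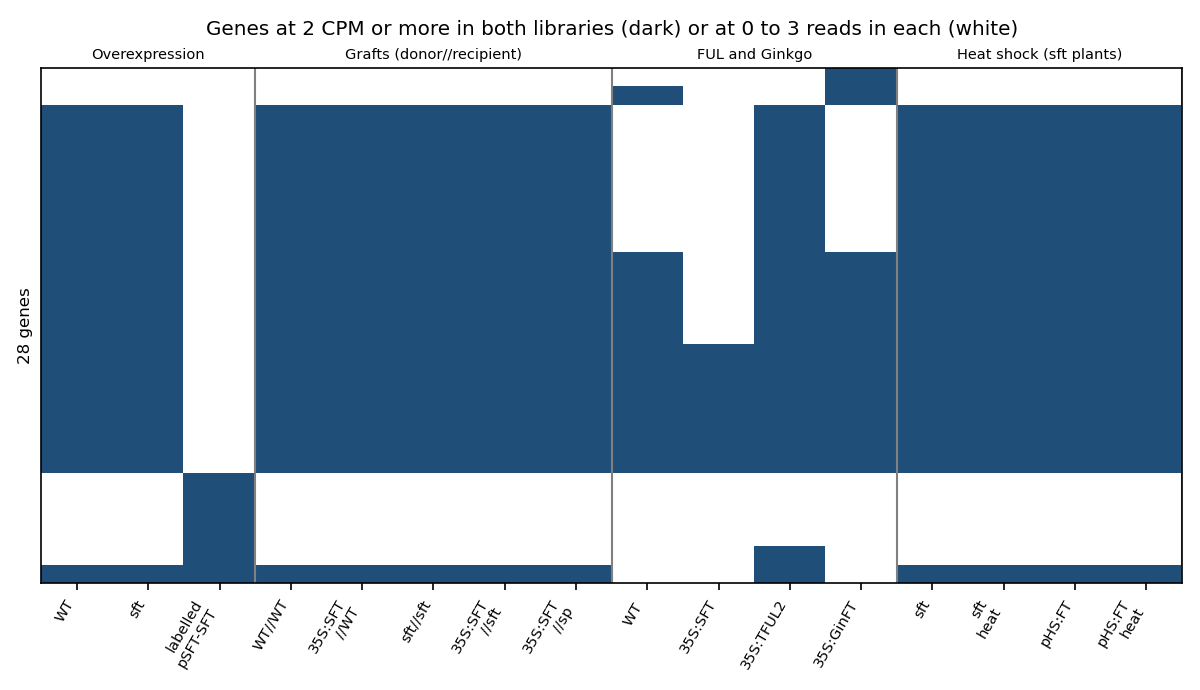
The 28 genes that were at 2 CPM or more in both libraries of a group (dark) or at 0 to 3 reads in each (white), one line per gene and one column per group. The column of the libraries labelled pSFT-SFT differs from the WT column beside it at 25 genes, and the WT columns of the overexpression and FUL experiments differ at 10.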

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

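The tests of explanations for the Arabidopsis FT reads were chosen after the reads were seen; the test of the difference in heat response and the left-out libraries were planned. With 2 libraries per group, no group was large enough to look for single outlying libraries.

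The response to heat differed between pHS:FT and sft plants by log2 4.49 at Solyc02g084790, by 3.14 at Solyc05g052400 and by 1.7 at Solyc06g007240, the 3 genes that the test of the difference itself called. With heat in sft plants the log2 change of Solyc02g084790 was -4.24 (adjusted p = 0.013). Solyc06g007240 is also 1 of the 15 genes that were higher at an unadjusted p under 0.05 in each of 4 florigen comparisons.

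An unheated sft library (replicate 1) held 12 reads on the Arabidopsis FT row, where the heated sft libraries held 0 and the other unheated sft library 0. A label swapped with a heated pHS:FT library is argued against, because its FT level was 0.17 times that of the lower heated pHS:FT library (95% interval 0.081 to 0.31) and the heated pHS:FT libraries held 57 and 70 FT reads, so neither is out of place as its partner. Intervals on the FT row cover counting error only. Mixing with a heated pHS:FT library stays open: the FT row implies 12.5% foreign reads (6.31% to 22.7%), and 102 genes raised 4-fold or more by heat in pHS:FT plants imply a median of 7.4% (4.8% to 10.8%), though FUL1 and FUL2 alone would need 48.8% and 26.4%. Plants with an active pHS:FT transgene in the sft pool also stay open: FUL1 was 16.3 times and FUL2 2.78 times as high as in the other unheated sft library, but with 1 library on each side this cannot be told apart from variation between pools. Counts of changed genes with either unheated sft library left out rest on a lone unheated sft library. They therefore cannot tell whether this library is the one out of place.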

How the results depend on the processing

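The alternatives below were listed before the data were examined, except the left-out libraries for the correlations, which were chosen after seeing the data. So was the run without unheated sft replicate 1 for heat in pHS:FT plants and for pHS:FT against sft with heat. For the other heat-shock counts that run was planned. Of 18 counts of changed genes, 18 stayed within 1.5 times under DESeq2-style size factors and 18 under a filter of 1 CPM in 2 libraries. Where another setting moved a count, the cause was not tested unless stated. With 2 libraries per group, leaving one out leaves a lone library that is assumed to vary like the other groups. Fewer residual degrees of freedom are thus built into that setting, though several counts rose under it. The p-values measure only the spread between duplicates. Depth limits genes near the floor of 0.0655 to 0.181 CPM, among them MBP20 and SP. The gene lists and the secondary wall list were not run under any setting, because the files do not pair identifiers with names.

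DESeq2 called 82 genes for sft against WT (12 in edgeR), 42 for 35S:SFT//sft (0), 90 for 35S:SFT//WT (3), 117 for sft//sft against WT//WT (2), 19 for the difference between recipients (0), 15 for 35S:SFT//sp (1), 1487 for 35S:SFT (370), 3064 for 35S:SFT against 35S:TFUL2 (1818), 253 for heat in sft (20), 228 for the difference in heat response (3), 97 for pHS:FT against sft without heat (0) and 1007 with heat (491). Without a filter on low counts, sft against WT gave 23, 35S:SFT//sft 2, 35S:SFT//WT 5, 35S:SFT 630, heat in sft 53, the difference in heat response 25 and pHS:FT without heat 1. With only the groups compared in the fit, and so fewer residual degrees of freedom, sft gave 0, 35S:SFT//WT 0, sft//sft 0, 35S:SFT//sp 0, 35S:SFT 18, 35S:TFUL2 1332, 35S:SFT against 35S:TFUL2 3466, 35S:GinFT against WT 172, heat in sft 7 and heat in pHS:FT 381. 

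Replicate numbers do not come from a stated batch, and correlations of the pairs' deviations lay from 0.08 to 0.25 in the overexpression, -0.51 to 0.43 in the graft, -0.14 to 0.3 in the FUL and -0.2 to 0.22 in the heat-shock experiment, so no experiment had every pair over 0.1. In the grafts the label numbers form an early and a late run, which crosses the replicate numbers for sp recipients. Paired by that run, a check added after seeing the data, the graft correlations lay from -0.04 to 0.51, with 8 of 10 pairs over 0.1 (4 of 10 by replicate number), a hint from the data that the runs differ. With the replicate number as a block, sft gave 4, 35S:SFT//sft 1, 35S:SFT//WT 0, 35S:SFT//sp 2, heat in sft 11, heat in pHS:FT 735, the difference in heat response 0 and pHS:FT with heat 315. With the run of library numbers in the labels as a block, 35S:SFT//sft gave 5, 35S:SFT//WT 12, sft//sft 7 and 35S:SFT//sp 2.

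Leaving out each library in turn gave 1270 to 2184 genes for the libraries labelled pSFT-SFT against WT, 1895 to 2501 against sft, 0 to 42 for sft, 0 to 2 for 35S:SFT//sft, 0 for 35S:SFT//WT and for sft//sft, 0 to 1 for the difference between recipients and for 35S:SFT//sp, 10 to 1339 for 35S:SFT, 280 to 3130 for 35S:TFUL2, 100 to 529 for 35S:SFT against 35S:TFUL2, 194 to 1595 for 35S:GinFT against WT and 2155 to 4699 against 35S:SFT, 0 to 146 for heat in sft, 31 to 2088 for heat in pHS:FT, 0 to 89 for the difference in heat response, 0 to 207 for pHS:FT without heat and 17 to 897 with heat.

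Correlations between florigen comparisons over genes with a mean log2 CPM of 3 or more were 0.287 (0.192 over all genes) for the libraries labelled pSFT-SFT with 35S:SFT//sft, 0.28 (0.244) with 35S:SFT and 0.185 (0.105) with the heat difference, 0.118 (0.068) for 35S:SFT with the heat difference, 0.143 (0.053) for 35S:SFT//sft with the heat difference, and 0.123 under both for 35S:SFT//sft with 35S:SFT. Leaving out libraries gave 0.041 to 0.231, 0.198 to 0.253, 0.078 to 0.119 and -0.001 to 0.156 for the first 4 in that order, -0.036 to 0.195 for 35S:SFT//sft with 35S:SFT, and -0.205 to 0.409 for 35S:SFT//sft with the heat difference. The last was negative without 9 libraries: 35S:SFT//sft replicate 1 (-0.205), sft//sft replicate 2 (-0.178), heated pHS:FT (-0.056 and -0.022), unheated pHS:FT (-0.068 and -0.069), heated sft (-0.067 and -0.06) and unheated sft replicate 2 (-0.125).

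Of 780 alternatives of 76 values of named genes, 647 kept direction and side of the threshold, 108 lost the call, 16 gained one and 9 turned direction, the latter among differences that were not called. Their ranges over left-out libraries were, for SFT, -0.21 to 0.14 in sft against WT (0.04 without sft replicate 2), -0.37 to 0.1 in 35S:SFT//WT and -0.04 to 0.96 in the heat difference; for FUL1, -0.17 to 0.06 in 35S:TFUL2 (0.04 without WT replicate 1) and -2.36 to 1.63 with heat in sft; and for MBP10 in 35S:TFUL2, 0.31 and 1.12 without a 35S:TFUL2 replicate and -0.04 without WT replicate 1 (the fitted 5.58 without WT replicate 2 is no bound, since replicate 1 alone held 0 reads). MBP20, at 1 or 2 reads in each sft and WT library, was too low for a fold, and its fitted values of -0.94 to 0.22, the latter without WT replicate 2, show no direction.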

Other observations

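The tests of the libraries labelled pSFT-SFT against a different genetic background, and the set tests, were chosen after the results were seen; those for a response to florigen and for the chromosome 6 stretch were written down before their values were computed.

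The heated pHS:FT genes set 35S:GinFT apart from the other FT comparisons. Of 163 genes called both in heated pHS:FT against sft plants and in 35S:GinFT against WT, 157 moved opposite ways and 6 the same way, where lists of these sizes would share 15.3 higher in the former and lower in the latter if independent, against 138 observed. Across genes r was -0.245. Genes higher in the libraries labelled pSFT-SFT than in both WT and sft (1606) were shifted downward in 35S:GinFT against WT: 254 of 1541 measured were called lower, 25 higher and 1262 neither, with a median of -0.22 (camera adjusted p = 9.8e-13, and adjusted p = 0.00054 with an estimated correlation). In heated pHS:FT against heated sft plants the list was shifted upward, with 245 of 1441 measured called higher, 0 lower and 1196 neither (median 0.39, adjusted p = 5.1e-40, and adjusted p = 0.0015 with an estimated correlation). They were already shifted upward in pHS:FT against sft plants without heat, where the Arabidopsis FT row held 1 and 1 reads in pHS:FT libraries. There 72.7% had a positive fold change, with a median of 0.18 (camera adjusted p = 8.4e-19, and adjusted p = 0.0061 with an estimated correlation). Of the 1441 measured, 0 were called higher and 0 lower. The 1456 genes lower in the libraries labelled pSFT-SFT than in both WT and sft had a median of 0.06 in 35S:GinFT against WT. Of 1411 measured, 95 were called higher and 54 lower. Camera did not call that list (adjusted p = 0.064, and adjusted p = 0.099 with an estimated correlation), while fry called it upward (adjusted p = 0.037). Because 35S:GinFT had no WT of its own experiment, no biological explanation of its opposite direction was tested.

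In the libraries labelled pSFT-SFT, 238 genes changed by 16-fold or more against WT, 117 higher and 121 lower. A response shared with a pulse of FT is argued against for the 126 of them measured in heated pHS:FT against heated sft plants, as a set. That comparison also holds any other difference between the lines. The median log2 change of the 126 genes there, taken in the direction seen in pSFT-SFT, was -0.01 (95% interval -0.16 to 0.14). The 5 of them called there nevertheless all moved the same way as in pSFT-SFT. A response to lasting florigen is not excluded by this. With a 35S:SFT donor the median was 0.18 (0.12 to 0.31) in sft recipients and 0.08 (-0.01 to 0.16) in WT recipients. A different genetic background of the plants may account for part of the 238 genes. This was tested only on those also called in 35S:TFUL2 against WT, with other libraries. Of 176 measured there, 97 were called, and 93.8% of these moved the opposite way (95% interval 87% to 97.7%). It was as if the alleles of one background stood on the transgenic side in one experiment and on the WT side in the other. Of 33 called in 35S:SFT against WT, however, 29 moved the same way. Of the remaining 3522 called genes, 5.8% of the 294 also called in heated pHS:FT plants moved the opposite way there, as did 27.5% of 131 in 35S:SFT, 49% of 864 in 35S:TFUL2 and 79.2% of 442 in 35S:GinFT, and no explanation was tested for those.

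In sft against WT stems, differences gathered on the part of chromosome 6 around SP, the antagonist of SFT. The stretch held the 200 tested genes nearest SP by identifier, 100 on either side. Of these, 23 (11.5%) had an unadjusted p under 0.01, against 251 of 20938 (1.2%) elsewhere (odds ratio 10.7, Fisher's exact p = 1.7e-15, genes not being independent replicates). In that stretch lay 4 of the 12 called genes. A chromosome segment carried along with the sft plants may explain this: the differences of these 23 genes returned in sft against WT recipients with a slope of 0.9 (95% interval 0.17 to 1.23; 22 of 23 in the same direction) and, with a 35S:SFT donor on both, of 1.1 (21 of 23). A response to the loss of florigen would predict a slope near 0 with that donor, and its lower bound was 0.28. That interval, 0.28 to 1.49, lies above 0. For these 23 genes as a set, this argues against a response that the donor fully reverses. The interval also spans the 0.5 that had been set, so a response reversed only in part cannot be told apart from a segment here.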
